A study of Mus musculus with 16 samples.

How the data were processed

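The samples were 16 libraries from 6 mouse lung adenocarcinoma cell lines. Per the labels, lines KL1, KL2 and KL3 carried KRAS G12V and had lost LKB1, and lines KP1, KP2 and KP3 carried KRAS G12V and had lost p53. Each line had been transduced with a tetracycline-inducible vector that was empty or encoded IFN-β or the STING mutant V154M, and all cells were kept in doxycycline at 1 µg/ml for 48 h. Polyadenylated RNA was made into 3′ mRNA libraries, in which reads fall near the 3′ end of a transcript. A 3′ read can miss an internal deletion, and it can miss a vector transcript whose 3′ end differs from that of the gene.

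The authors deposited a pair of tables with 1 column per library, whose unit is a signal of normalised read counts per gene. There were 18252 genes in 12 libraries for IFN-β and 16580 genes in 8 libraries for STING, and 4 empty-vector libraries stood in both. The column names of these 4 (KL1, KL2, KP2 and KP3) carry a suffix that the KL3 and KP1 empty columns lack. What it stands for is not stated. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.10b, HTSeq 0.12.4, DESeq2 1.30.1 and the mouse build GRCm39. The annotation for that build was not at hand, so genes are given by the symbols in the files and no coordinates are printed. Every deposited column was checked to be whole multiples of 1 step, within a tolerance of 0.05 reads, and the steps differed from DESeq2's median-of-ratios factors by at most 6.16e-05%. Dividing by the step gave the reads per gene. In 2 columns, the KP1 empty library of the IFN-β table and the KP2 STING library of the STING table, the step lay so near 1 that whole reads were not taken as established. Each gene in either table had at least 10 reads over its libraries. The reads of the 4 shared empty libraries differed in 0 of the 16505 genes present in both tables. The tables were normalised separately, so levels were compared inside 1 table only.

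Library totals ranged from 6.46 to 12.2 M reads (M, 1e6) in the IFN-β table and from 6.46 to 8.05 M in the STING table. Reads carry no molecular identifiers, so intervals (95%) and floors (3 reads where none was seen) cover counting error only. The p-values measure the spread between cell lines within a genotype, with each label taken as its own line. That is in doubt for KL1 and KL2, which may be the same cell line. It is also in doubt for the library labelled KL2 IFN-β, which may be of another line.

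Comparisons were fitted with limma 3.58.1 (limma-trend, Benjamini-Hochberg adjustment) in R 4.3.3 on the log2 of the deposited value plus 1. Genes with a mean of at least 10 over a table's libraries were tested, which left 12386 genes in the IFN-β table and 12062 in the STING table. The model had 1 mean per group of genotype and vector. The contrasts were each vector against empty (averaged over the genotypes with equal weight, and in KL and KP separately), the difference of that effect between KP and KL, and KP against KL with the empty vector. An adjusted p under 0.05 counted as called. The STING effect was set against the IFN-β effect on fold changes within the 4 lines that had both vectors, taken inside each table and paired by line, over 11910 genes. Gene lists (24) were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for lists with at least 5 members tested, and their members were also counted with p adjusted over the list alone. Sums of normalised counts over a list were compared between vectors by an exact two-sided sign-flip test over lines.

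The genes named by rule were, per comparison, those with a symbol, a mean of at least 20, a call, and the same direction in every line compared (for KP against KL, no overlap between the lines), ranked by size: up to 10 in each direction for IFN-β and 5 in each direction for KP against KL and for STING minus IFN-β. The groups, contrasts, lists, rule and most alternatives were fixed before the data were examined. With IFN-β 207 genes were eligible and 8 without a proper symbol were passed over. Genes singled out beyond the rule and the lists are said to be chosen after their values were seen.

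The labels give the same cell line for libraries with the same number, so the numbers pair the samples. Deviations of a line's vector library and empty library from their group means correlated across genes at 0.721 in KP1, 0.425 in KP2, 0.626 in KP3, 0.503 in KL1, 0.0963 in KL2 and 0.559 in KL3 in the IFN-β table. In the STING table the correlation was 0.758 for the KP lines and 0.268 for the KL lines. A fit with cell line as a block was therefore run as an alternative. Others were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, equal library totals, quantile normalisation, limma without the trend, edgeR 4.0.16 and DESeq2 1.42.0 on whole reads, a log2 size threshold of 1, and leaving out each library. The count tools were planned for the libraries with established whole reads. Runs with every library, the block without line KL2, the list tests, the list sums and the Ifnb1 bound without the library labelled KL2 IFN-β, the sum of interferon-stimulated genes below the minimum mean, and the KP reference for shared empty libraries were added after the data had been seen. With equal library totals the median log2 fold change of all genes was 0.155 for KP against KL (0.018 in the main fit). It was 0.156 for STING in KL (-0.0306 in the main fit). For the difference of the STING effect between genotypes it was -0.19 (0.0439 in the main fit).

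The fits were tested on simulated data with 200 changed genes. Without the block, the average IFN-β contrast recovered 12.5% of genes raised 2-fold, 77.5% of those raised 4-fold and 90% of those raised 8-fold, with 0 false calls. The average STING contrast recovered 10%, 77.5% and 95%. For STING in KL the shares were 0%, 32.5% and 65%. With the block, STING in KL recovered 77.5% of genes raised 2-fold, with 24 false calls among 188. In a single simulated table with no list changed, camera called none. Each gene was drawn independently there, so this run cannot test the preset inter-gene correlation. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.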

Results

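Gene expression was measured by 3′ mRNA sequencing in mouse KRAS-mutant lung tumour cell lines 48 h after a vector had been switched on, to see what IFN-β and constitutively active STING do in tumour cells that lack LKB1 (KL) or p53 (KP). The empty vector and IFN-β were each measured in 3 KL and 3 KP lines, and STING V154M in 2 KL and 2 KP lines (KL1, KL2, KP2 and KP3). Empty libraries held 6.46 to 8.05 M reads (n = 6), IFN-β libraries 7.35 to 12.2 M (n = 6) and STING libraries 6.66 to 7.51 M (n = 4). Ribosomal Rn18s-rs5 took 3.57% of reads in the KL1 IFN-β library and 12.6% in the KL1 empty library, the lowest and highest shares.

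The deleted tumour suppressors marked the genotypes. Trp53, which encodes p53, stood at 366 ± 45.1 normalised counts in KL empty libraries and 6.71 ± 6.24 in KP (SD, n = 3 each; log2 difference -6.22 ± 0.75 SE, adjusted p = 0.00125). Stk11, which encodes LKB1, was lower in KL, at 176 ± 8.63 against 601 ± 68.4 in KP (1.76 ± 0.20, adjusted p = 0.000884). Ifnb1 had 0 reads in the 6 empty libraries and 89 in the 6 IFN-β libraries, at least 24.6-fold higher against a floor of 3 reads over the group. The KL IFN-β libraries held 76 of these reads, 58 of them in the library labelled KL2, and the KP ones 13. Without that library 31 reads remained, 18 of them in KL, and the group was at least 10.6-fold higher. Sting1 was at 42.6 ± 43.0 in empty and 51.3 ± 43.7 in STING libraries (SD, n = 4 each; log2 0.44 ± 0.33), which did not pass limma's test, and reads at the 3′ end need not report the vector's transcript.

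IFN-β raised the interferon-stimulated genes together. Of 49 members tested, 48 rose (49 adjusted over the list alone), with a median log2 fold change of 6.71, or 6.89 with members absent from the empty libraries at their bound. Ifi44 went from 1.11 ± 1.16 to 2489 ± 734 normalised counts (SD, n = 6 each; log2 10.33 ± 0.26 SE, adjusted p = 3.7e-10). Isg15, the ubiquitin-like modifier, went from 5.56 ± 6.79 to 4441 ± 1110 (9.92 ± 0.41), and the antiviral genes Ifit1, Ifit3, Ifit3b, Rsad2, Oasl2, Trim30a and the GTPase Gbp3 also rose by 9.33 to 10.26, each in 6 of 6 lines. Gbp3 had 3 reads in the empty libraries, so its ratio of 1845 has a counting interval of 631 to 8950. The list's summed counts rose 19.7- to 79.9-fold within lines (median 35.8; 6 of 6; exact two-sided p = 0.03125, the smallest that 6 lines allow). Without the pair labelled KL2 the range was 19.7 to 73.5 (median 28.9; 5 of 5; exact two-sided p = 0.0625, the smallest that 5 lines allow). In camera the list's adjusted p was 1.65e-177, and 0.000467 with an estimated correlation.

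**Figure D1:**
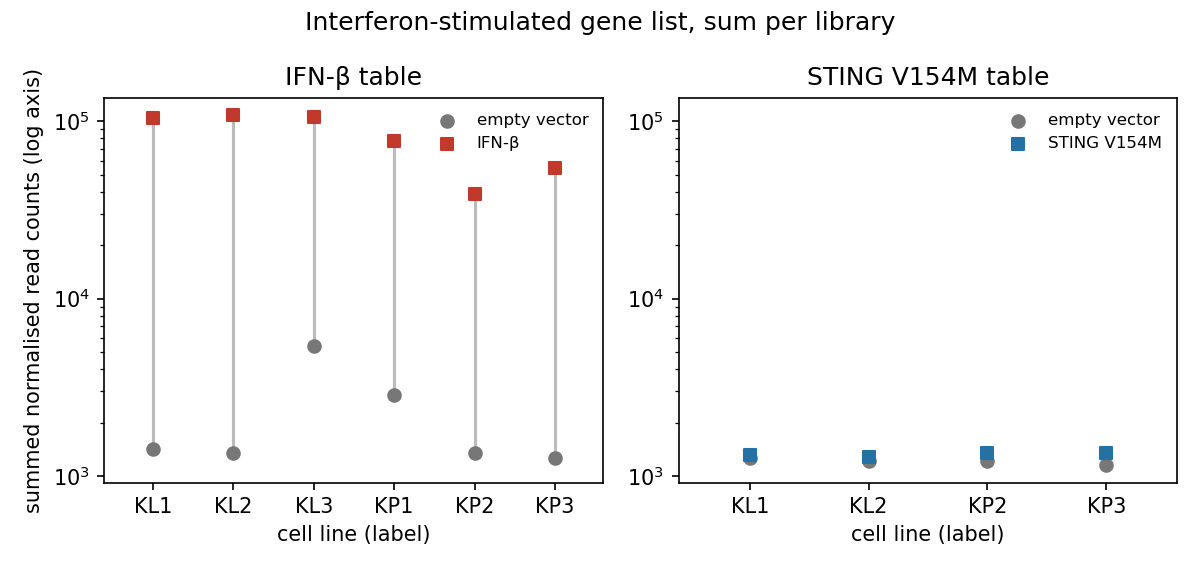
Summed normalised read counts of the interferon-stimulated gene list (log axis) in each cell line, in the IFN-β table (left) and the STING table (right), with 1 point per library and a grey line joining the vector to the empty library of the same line. Over the 49 members in the IFN-β table, IFN-β libraries stand at 19.7 to 79.9 times their empty libraries. Over the 34 members in the STING table, STING libraries stand at 1.04 to 1.17 times theirs.

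Some of the genes that carry and sense interferon signals rose with it. Among signalling components 6 of 17 rose (6 adjusted over the list alone), including the transcription factors Irf7 (9.59 ± 0.38), Stat1 (4.82 ± 0.16; 48.5 ± 13.6 to 1406 ± 449) and Stat2 (4.65 ± 0.17) and the feedback inhibitor Usp18 (8.04 ± 0.48). Among nucleic acid sensing genes 10 of 21 rose (10 over the list alone), such as the DNA-binding Ifi203 (7.65 ± 0.56), Zbp1 (6.89 ± 0.39) and Dhx58 (5.62 ± 0.41). In MHC class I antigen presentation 13 of 18 rose (15 over the list alone). These included the immunoproteasome subunit Psmb8 (7.80 ± 0.56), the peptide transporter Tap1 (7.49 ± 0.60), the transactivator Nlrc5 (6.37 ± 0.41) and the light chain B2m, from 1275 ± 1050 to 29386 ± 13104 (4.78 ± 0.40). Psmb9 had 0 reads in the empty libraries and was at least 151-fold higher against a floor of 3 reads over the group. Camera called all 3 lists, with adjusted p of 0.0128 for signalling, 0.000511 for sensing and 0.000511 for MHC class I with an estimated correlation. With cell line as a block as well, signalling missed the threshold (0.143) and sensing and MHC class I kept it (0.0345 each).

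Genes through which tumour cells meet lymphocytes changed in part. The T cell attractant Cxcl10 rose from 2.59 ± 2.73 to 1039 ± 521 (8.32 ± 0.63, adjusted p = 2.89e-06), 1 of 4 chemokines tested, while Ccl5 was at 1.77 ± 0.93 (adjusted p = 0.837). Of 9 checkpoint ligands 3 rose (camera adjusted p = 3.16e-06, and 0.0137 with an estimated correlation, or 0.0941 with the block as well): Cd274, which encodes PD-L1, from 27.4 ± 11.9 to 522 ± 281 (4.14 ± 0.35), Lgals9 (3.61 ± 0.17) and the phagocytosis inhibitor Cd47 (1.33 ± 0.23). Of 22 cell death genes 4 rose (6 adjusted over the list alone; camera adjusted p = 2.58e-07, and 0.00522 with an estimated correlation), namely Xaf1, the sensor Zbp1, Daxx (1.56 ± 0.25) and the necroptosis effector Mlkl (1.51 ± 0.20). The complement factor Cfb rose by 3.75 ± 0.53, 1 of 5 complement genes (camera adjusted p = 0.0129, and 0.0891 with an estimated correlation). None of 3 MHC class II genes was called.

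Other programmes moved little. Csf1, a macrophage growth factor, rose by 1.55 ± 0.24, 1 of 31 NF-κB targets, and the list's camera p of 0.00763 became adjusted p = 0.194 with an estimated correlation. The unfolded protein response (0 of 24 members; 0.0455) and p53 targets (0 of 29; 0.0102) had adjusted p of 0.423 and 0.725 with an estimated correlation. Without the library labelled KL2 IFN-β the p of these 3 lists was 0.0738, 0.31 and 0.14. In glycolysis 2 of 18 rose: Pfkfb3 by 0.93 ± 0.18, and Hk2 by 0.70 ± 0.15 (adjusted p = 0.0405, and 0.0806 with cell line as a block). Leaving out 1 library ended the call of Pfkfb3 in 4 of 12 runs (adjusted p up to 0.0605, without KP3 IFN-β) and that of Hk2 in 10 (up to 0.13, without KL1 empty). Limma called no member among 42 cell cycle genes (camera adjusted p = 0.107), 24 cholesterol synthesis genes (0.414), 26 oxidative phosphorylation genes (0.286) or 16 genes of serine metabolism (0.707). Without the library labelled KL2 IFN-β, cell cycle was higher and cholesterol synthesis lower in camera, at 0.0196 and 0.000277, with adjusted p of 0.653 and 0.338 with an estimated correlation. The same count of 0 held for 19 epithelial (0.693), 18 mesenchymal (0.221) and 32 ribosomal protein genes (0.979), and for 3 leukocyte, 2 endothelial and 2 fibroblast markers, except that the block called the epithelial mucin gene Muc1 higher (0.77, adjusted p = 0.0271), chosen after its values were seen. Summed leukocyte markers were 3.48 and 3.05 times their empty level in KL1 and in the libraries labelled KL2, and 0.605 to 1.39 times in the other lines (exact two-sided p = 0.281). Mitochondrially encoded genes were lower as a list (camera adjusted p = 0.008, and 0.194 with an estimated correlation) with 0 of 9 members called in limma over all genes, 1 adjusted over the list alone, and 1 with the block, mt-Nd6 (-0.99, adjusted p = 0.0436), also chosen after its values were seen. Their sum was 0.283 times the empty level in KL1, 0.687 in the libraries labelled KL2 and 0.909 to 1.09 in the other lines (exact two-sided p = 0.219).

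Fewer genes fell, and by less. Card14 (-1.71 ± 0.31), Stc1, which encodes the secreted hormone stanniocalcin (-1.71 ± 0.33), Sema4b (-1.02 ± 0.17), the RNA polymerase III subunit gene Polr3g (-0.998 ± 0.19) and Fam199x (-0.71 ± 0.13) fell in 6 of 6 lines. The other genes called lower were Nptx1, a neuronal pentraxin, from 61.1 ± 48.0 to 7.83 ± 7.55 (-2.69 ± 0.53, adjusted p = 0.0163), the mitochondrial transfer RNA mt-Tq (-1.56 ± 0.33), Dbn1 (-1.08 ± 0.22), the histone gene H2aj (-0.76 ± 0.16) and Gan (-0.67 ± 0.15). These lost their call when 1 library was left out: Nptx1 in 5 of 12 runs (adjusted p up to 0.0652, without KL1 empty), mt-Tq in 8 (0.0863, without KL2 IFN-β), Dbn1 in 10 (0.0923, without KL1 empty), H2aj in 7 (0.0795, without KL2 IFN-β) and Gan in 12 (0.151, without KL1 empty).

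**Figure D2:**
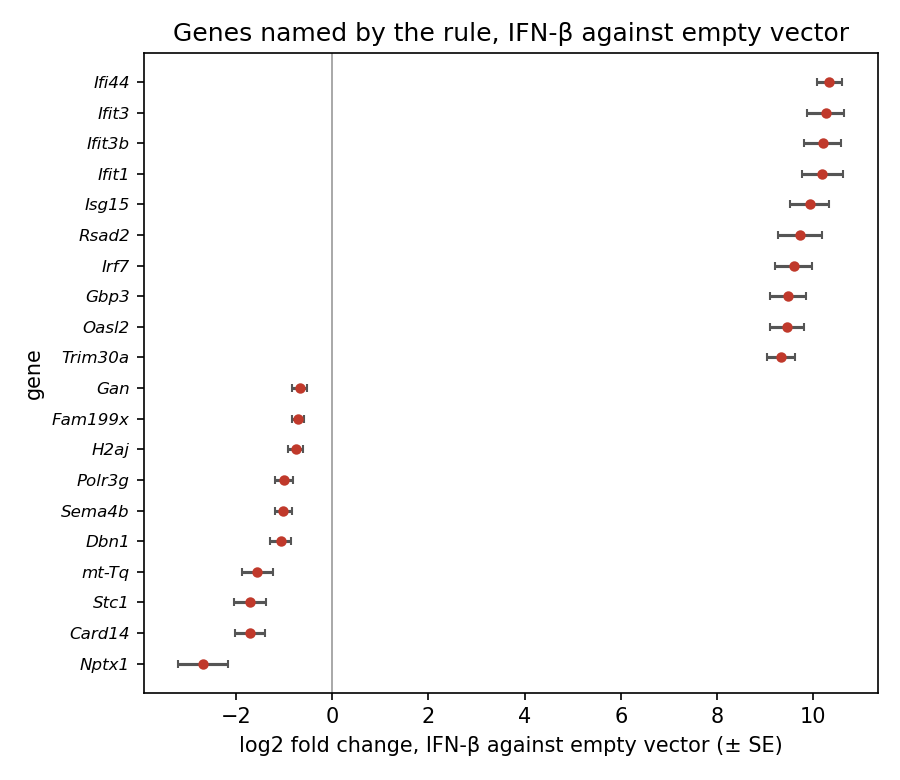
Fitted log2 fold change of IFN-β against the empty vector (horizontal axis) for the 10 genes with the largest rise and the 10 with the largest fall named by the rule; points are estimates over 6 lines and bars are ± 1 SE. The genes that rose lie between 9.33 and 10.33, and those that fell between -2.69 and -0.67.

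In all, limma called 220 of 12386 genes with IFN-β, 210 higher and 10 lower, and 292 with cell line as a block (261 higher, 31 lower). Without the library labelled KL2 IFN-β it called 189, and 47 of the interferon-stimulated genes rose.

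The response was measured in both genotypes. In KL lines 185 genes were called (180 higher, 5 lower) and in KP lines 134 (134 higher, 0 lower), and in each 45 of 49 interferon-stimulated genes rose. The library labelled KL2 IFN-β differed from its partners in sex-linked genes: the non-coding RNA Xist was at 4050 normalised counts against 0 in the KL2 empty library, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0 against 337. Without that library KL lines had 132 genes called. The difference between genotypes was tested itself, and limma called 0 genes (226 at an unadjusted p under 0.05). The block and edgeR also called 0, and DESeq2 called 0 without the KP1 empty library and 1 with it. That gene, Trim12c, was chosen after its values were seen (3.21, adjusted p = 0.00383 in DESeq2). Camera called 10 of 19 lists in this difference. The interferon-stimulated genes had a median of -0.65 in KP relative to KL (adjusted p = 0.00188) but 0.5 with an estimated correlation and 0.121 without the library labelled KL2 IFN-β. No list was called with an estimated correlation.

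**Figure D3:**
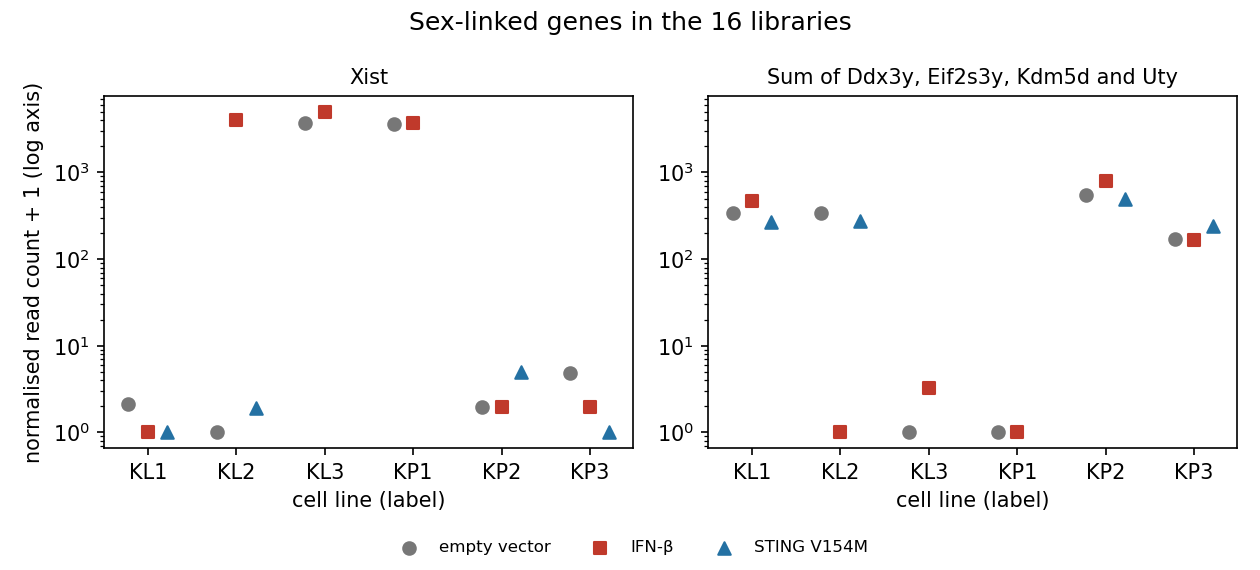
Normalised read count plus 1 (log axis) of Xist (left) and of the sum of 4 Y-linked genes (right) by cell line label, with 1 point per library; STING points come from the separately normalised STING table. The KL2 IFN-β point lies at 4050 for Xist and 0 for the Y-linked sum, and the KL2 empty point at 0 and 337.

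With the empty vector, single genes set KP and KL lines apart. KP lines expressed the hepatocyte and gut transcription factor gene Hnf4a (199 ± 96.6 normalised counts against 0.379 ± 0.656 in KL, SD, n = 3 each; adjusted p = 0.000134), the retinol carrier Rbp4 (349 ± 82.5 against 0.757 ± 1.31), Lgals2 (482 ± 193 against 0), the apolipoprotein Apob (log2 7.31 ± 0.96) and the growth factor binding protein Igfbp4 (7.76 ± 1.06). KL lines expressed Tmem252 (470 ± 58.4 against 0.648 ± 1.12), Trp53i11 (194 ± 115 against 0.648 ± 1.12) and Pdzrn3 (189 ± 264 against 0), and had more of the complement regulator Cd55 (-3.96 ± 0.35 for KP minus KL), the adhesion molecule Ceacam1 (-4.96 ± 0.62) and the kinase Ikbke (-2.27 ± 0.31). The rule also named Ccnd2, encoding cyclin D2 (7.76 ± 1.65, adjusted p = 0.0246), and Krt6a (-6.95 ± 1.76, adjusted p = 0.0493). Leaving out 1 library ended the call of Ccnd2 in 5 of 6 runs (adjusted p up to 0.0962, without KL1 empty) and that of Krt6a in 6 (0.147, without KP1 empty).

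Gene lists showed few shared differences between genotypes. Of 49 interferon-stimulated genes 2 were higher in KP and 2 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.544); the GTPase Ifi47 was at 22.7 ± 13.4 in KP and 0.352 ± 0.609 in KL. Of these 4 calls only that of Ifi47 held in every run with 1 library left out: Ifit2 lost its call in 4 of 6 runs (adjusted p up to 0.144, without KP1 empty), Mx1 in 5 (0.0834, without KL2 empty) and Rsad2 in 5 (0.129, without KP2 empty). Cell death had 3 of 22 genes lower, and Casp8 (up to 0.125, without KP3 empty), Bcl2l1 (0.137, without KL2 empty) and Mlkl (0.135, without KL1 empty) each lost the call in 5 of 6 runs. The p53 targets, checkpoint ligands and nucleic acid sensing had 1 lower each (that of the p53 target Polk was lost in 6 of 6 runs, up to 0.128 without KP1 empty), and MHC class I had 0 of 18 called. Complement and mesenchymal genes had 1 higher and 1 lower each, and epithelial markers 2 higher and 1 lower; the calls of Sparc and Zeb1 were lost in 4 of 6 runs each (up to 0.102, without KL2 empty, and 0.093, without KP1 empty), Foxa2 in 3 (0.0681, without KL2 empty) and Krt7 in 2 (0.0655, without KL2 empty). Serine metabolism (adjusted p = 0.00254, median 0.59) and cholesterol synthesis (0.0138, median 0.52) were higher in KP as lists, but both had adjusted p = 0.758 with an estimated correlation. Limma called 490 genes, 223 higher in KP and 267 lower. Leaving out 1 empty library gave 150 (KL2), 156 (KP1), 171 (KL1), 194 (KP3), 225 (KP2) or 1214 (KL3). The STING table, which lacks KL3 and KP1, gave 1552, but its KL1 and KL2 libraries may come from the same cell line. Their empty libraries are also part of the main comparison, so its KL group may hold fewer than 3 independent lines. In the IFN-β table scaled to equal totals, 279 were higher and 184 lower, so the balance of directions turned.

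With STING V154M the interferon-stimulated genes moved far less than with IFN-β. Their sum covered the 34 members in the STING table, against 49 in the IFN-β table. Abundant members such as Trim25 (a mean of 427 normalised counts) weigh most in it. The summed counts of the interferon-stimulated genes were 1.04 to 1.17 times those in the empty library of the same line (median 1.08; higher in 4 of 4 lines; exact two-sided p = 0.125, the smallest that 4 lines allow), and on average over the genotypes limma called none of the 16 members abundant enough to test, with or without cell line as a block (camera adjusted p = 0.162). In KL alone the block called 1 of them, Rsad2 (2.59 ± 0.58, adjusted p = 0.0464), which was chosen after its values were seen, and limma without it called 0. The 18 members below the minimum mean summed to 1.06 to 1.62 times the empty level (median 1.38; exact two-sided p = 0.125), and none was called without the filter. Of 34 members in the table, 6 were higher and 2 lower (Eif2ak2 and Zbp1) in 4 of 4 lines. Among those higher, chosen after their values were seen, Isg15 was at 3.25 ± 1.03 in empty and 9.82 ± 5.39 in STING libraries, Ifit1 at 0.691 ± 0.466 and 6.95 ± 1.77, and Rsad2 at 3.93 ± 4.33 and 24.3 ± 29.0 (SD, n = 4 each). The lymphocyte-attracting chemokine Cxcl10 was at 1.92 ± 2.47 in empty and 28.3 ± 16.5 in STING libraries (SD, n = 4 each; log2 3.54 ± 0.79) and Ccl5 at 2.86 ± 2.16 and 83.9 ± 64.1 (3.94 ± 0.93), each higher in 4 of 4 lines. Leaving out 1 library gave 2.88 (without KP2 empty) to 4.20 (without KP3 empty) for Cxcl10, and 2.81 (without KP3 STING) to 5.08 (without KP2 STING) for Ccl5. Both missed the threshold over all genes in limma and passed it when adjusted over the list alone, as 2 of 4 chemokines. NF-κB targets, which include the neutrophil attractant Cxcl1, were higher as a list (adjusted p = 0.0201, and 0.417 with an estimated correlation), as were cell cycle (0.00171; 0.807) and oxidative phosphorylation genes (0.000125; 0.417). In KL the medians of these lists were 0.25, 0.25 and 0.49, and in KP they were -0.04, 0.04 and 0.03, where none was called (adjusted p = 0.908, 0.908 and 0.587).

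Over all 12062 genes limma called 0 with STING V154M (351 at an unadjusted p under 0.05), as did the block (1390 unadjusted) and edgeR. DESeq2 called 2 genes without the KP2 STING library, where KP3 alone stands for STING in KP and the other groups supply the spread: Cxcl10 (4.40, adjusted p = 0.0147) and Ccl5 (5.53, adjusted p = 1.86e-12), which were chosen after their values were seen, and 0 with every library, where their adjusted p was 0.222 and 0.371. Without the KL1 empty library, which leaves KL2 alone as the KL empty group, limma called 23 genes.

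Within genotypes, limma called 0 genes with STING V154M in KL (1412 unadjusted) and 0 in KP (97 unadjusted). The KL libraries, labelled KL1 and KL2, may come from the same cell line, so their spread may be that of replicates of a line. In KL the counts of other fits varied: 597 genes with cell line as a block (445 higher, 152 lower), 119 in DESeq2, 0 in edgeR, 1 in limma without the trend, and 322 in limma without the KL1 empty library, where 1 KL empty library remains and the other groups supply the spread. With the block and equal library totals 1022 genes were called. With the block alone, 9 of 26 oxidative phosphorylation genes were higher and 1 lower, and 6 of 42 cell cycle genes, 5 of 32 ribosomal protein genes and 5 of 27 NF-κB targets were higher (adjusted p = 0.774 for each list with an estimated correlation). The unfolded protein response had 2 genes higher and 4 lower, cell death and p53 targets 1 higher and 2 lower each, and serine metabolism 2 higher and 2 lower. Socs3 (2.33 ± 0.46, adjusted p = 0.0391) and B2m (1.23 ± 0.26, adjusted p = 0.0425) were the single members called in interferon signalling and MHC class I, chosen after their values were seen, and Cxcl10 rose by 3.94 ± 0.53 (adjusted p = 0.0281). Rn18s-rs5 took 12.6% and 10.4% of reads in the KL1 and KL2 empty libraries, and at most 9.79% in the STING libraries. In KP the block and edgeR gave 0 and DESeq2 gave 1, Ccl5 (6.44, adjusted p = 4.72e-05), chosen after its values were seen and resting on the KP3 STING library alone, or 0 with every library. The effect in KP minus that in KL had 0 genes called (934 unadjusted; edgeR 0; block 7; DESeq2 52 without the KP2 STING library; 179 without the KL1 empty library). The single gene that limma without the trend called in KL and in this difference was Mir703 (4.18 and -6.24), chosen after its values were seen.

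The test of STING V154M against IFN-β, paired by line label, separated them at the interferon genes. The library labelled KL2 IFN-β may be of another line, and the other KL1 and KL2 libraries may be of the same line. The 4 lines behind its p-values may thus not be 4 independent pairs. All 16 interferon-stimulated genes tested were lower with STING (median log2 difference -4.73; 16 adjusted over the list alone; camera adjusted p = 0.042 with an estimated correlation), as were 8 of 12 MHC class I genes, 7 of 18 sensing genes (adjusted p = 0.042 for each list with an estimated correlation) and 3 of 9 checkpoint ligands (adjusted p = 0.244 with an estimated correlation). Stat1 was lower by -5.14, B2m by -4.60, Cd274 by -4.22 and Cxcl10 by -5.40 (adjusted p = 0.00111), each in 4 of 4 lines. The rule named the tetherin gene Bst2 (-5.87 ± 0.35), Samd9l (-5.51 ± 0.31), Mndal (-6.77 ± 0.50), Parp9 (-7.80 ± 1.10) and Slfn9 (-6.02 ± 1.04) among genes lower with STING, and mt-Tq (2.05 ± 0.19), Nptx1 (3.08 ± 0.51), Upp1 (1.52 ± 0.21), the angiogenic factor gene Pgf (1.38 ± 0.22) and Dhrs9 (1.27 ± 0.20) among those higher. Leaving out 1 line ended the call of Parp9 in 1 of 4 runs (adjusted p = 0.171 without KL1), of Slfn9 (up to 0.348, without KL1), Nptx1 (0.312, without KL1) and Upp1 (0.103, without KP3) in 2 runs each, and of Pgf (0.141, without KP3) and Dhrs9 (0.208, without KL1) in 3.

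This test called 100 of 11910 genes, 6 higher and 94 lower with STING. It called 65 without pairing by line, all of them lower, 49 without line KL1, 64 without line KP3 and 120 without line KL2. Camera called 10 lists, and 3 with an estimated correlation.

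Across genes, the STING and IFN-β fold changes correlated at r = 0.277 (rho = 0.34), where genes are not independent replicates. Both are measured against shared empty libraries, and simulated vectors with no effect gave 0.409 (0.362 to 0.46) from that sharing alone. The simulation gave all libraries equal noise for a gene and held no IFN-β effects, so its r is not directly comparable with the observed one. The covariance was 0.0371 observed and 0.0374 simulated. With disjoint lines, which share no control, r was -0.03 over all genes and 0.608 (rho = 0.347) over the 16 interferon-stimulated genes.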

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

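The tests of the lines behind the libraries labelled KL2, of the interferon response with STING V154M and of other splits were chosen after the results had been seen. So was the KP reference for the genes called in KL with the block, whose other tests were set before.

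The library labelled KL2 IFN-β held Xist at 4050 normalised counts and 0 Y-linked reads, while the KL2 empty and STING libraries held Y-linked reads and next to no Xist. An effect of interferon on these genes is argued against by KL1, KP2 and KP3, where the Y-linked sum with IFN-β was a median of 1.41 times that with the empty vector. A mixed culture is argued against by the 0 Y-linked reads where 433 were expected, which allow at most 0.693% of cells like those of the KL2 empty library. A candidate explanation is that this library came from another cell line: 484 genes stood 4-fold or more apart between KL1 and KL2 with IFN-β and 166 with the empty vector, a larger factor than for any pair of lines without KL2. Stk11 (147) and Trp53 (291) in this library were at KL levels. KL3 libraries also held Xist (3713.6 empty, 4921.5 IFN-β). Its p53 target sum (22888) lay near KL3 (23082.5 empty, 23813.6 IFN-β) and far from KL2 empty (6949). Its MHC class I sum (95552) lay nearer KL1 IFN-β (99603.5) than KL3 IFN-β (47618), as did its leukocyte sum. Which line it came from was not tested. If it came from KL3, the KL IFN-β libraries hold fewer than 3 independent lines. The KL1 and KL2 libraries of the STING table may in turn come from 1 cell line. Between them 2 genes differed 4-fold or more in the same direction with both vectors, against 99 between KP2 and KP3. Other values do not settle it. With the empty vector 135 genes stood 4-fold apart between KL1 and KL2, and 160 between KP2 and KP3. Differences between KL1 and KL2 correlated at r = 0.379 between the empty and STING libraries. For KP2 and KP3 that r was 0.838, and 0.357 between their empty and IFN-β libraries. Distinct or closely related lines thus stay open.

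With STING V154M limma called no interferon-stimulated gene on average over the genotypes, and with the block in KL it called 1 (Rsad2, adjusted p = 0.0464). Isg15 (3.25 ± 1.03 to 9.82 ± 5.39) and 5 other members of 34 were higher and 2 lower in 4 of 4 lines. That too few libraries hid a response of the size seen with IFN-β is argued against by the test of the difference, in which 16 of 16 of those tested were lower with STING; a smaller response stays open. Whether STING V154M was expressed cannot be told apart from its being expressed with little effect, since Sting1 had a log2 fold change of 0.44 and the 3′ reads may miss the vector's transcript. Cxcl10 and Ccl5 were higher in 4 of 4 STING lines, and with every library neither was called on average over the genotypes.

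Cell line as a block gave 597 genes called with STING V154M in KL, where limma without it called 0. The deposited scaling is argued against as the whole cause, since 512 of these genes were still called with equal library totals, although 1022 genes were called in all, so scaling moved the count. Whether the KL1 and KL2 empty libraries stand apart cannot be told apart from the effect of sharing them. The shared empty libraries are also the ones with a suffix in their column names, so a difference tied to that suffix cannot be separated either. Of these genes 90.1% moved the same way with IFN-β in KL1 and KL2, which share those empty libraries, 9.88% in KL3 and 51.6% in the KP lines, but in KP, where no gene was called, as many genes of lowest p gave 71.4% with the shared empty libraries and 25.3% in KP1. A shared effect of both vectors in these lines stays open and was not tested.

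Other splits of the libraries were counted for each comparison. With IFN-β, 1 of 100 splits drawn from 200 gave as many as the 220 genes of the real one. The highest other gave 203, for the KP1 and KL1 pairs with KP2 empty and KL2 empty against the rest. This count thus hardly sets the vector apart from the structure of the lines. With pairs parted and the block, 1 of 32 splits gave as many (292, highest other 0). That share needs the pair labelled KL2 to be from 1 line, which is in doubt. Without that pair no share under 0.05 is possible with pairs parted, so chance is not called excluded there. Nor is it called excluded for the 100 splits, where the highest other count came near the real one. The other designs have too few splits for a share under 0.05. In KL with IFN-β 2 of 10 splits gave as many (185 real; 357 for KL1 empty, KL1 IFN-β and KL2 empty against the rest, which points to a structure of the lines), and in KP 1 of 10 did (134; highest other 0). With STING V154M 18 of 18 gave at least the real 0, up to 954 for KP2 and KL1 against KP3 and KL2, again a structure of the lines, and 8 of 8 with pairs parted and the block (0; up to 7). For the IFN-β effect in KP minus KL it was 10 of 10 (0; highest other 0), for KP against KL 1 of 10 (490; highest other 2), and for STING minus IFN-β 1 of 8 (100; highest other 0).

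Of 38 measures, taken of libraries and of the fold changes of single genes over lines, 3 were flagged, all of them measures of libraries. Chance gives about 1 in 20 for each measure. Fewer than 38 measures were of libraries, and the flags of the KL1 IFN-β library overlap, so no rate is compared with that. The KL2 empty library had the lowest total of the 6 empty libraries, 6464486 reads. The KL1 IFN-β library had the lowest share of Rn18s-rs5 (3.57%) and of the 10 most abundant genes (12.03%) of the 6 IFN-β libraries.

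The IFN-β effect differed between genotypes, by camera with the preset correlation, in 10 lists. Their median differences of KP minus KL were -0.65 for interferon-stimulated genes, -0.42 for interferon signalling, -0.40 for nucleic acid sensing, -0.26 for NF-κB targets, -0.58 for checkpoint ligands, 0.20 for cell cycle, -0.71 for p53 targets, -0.63 for cholesterol synthesis, -0.40 for serine metabolism and -1.17 for complement. With an estimated correlation the adjusted p was 0.186 for complement, 0.539 for p53 targets and 0.5 for the others. Without the library labelled KL2 IFN-β all but checkpoint ligands, cell cycle and complement missed the threshold, and oxidative phosphorylation passed it (0.0159), with adjusted p of 0.432 or more for each with an estimated correlation. The STING effect differed in cell cycle (-0.29) and oxidative phosphorylation (-0.43), with adjusted p of 0.843 and 0.721 with an estimated correlation.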

How the results depend on the processing

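Runs of the count tools with every library, the block without line KL2 and the list tests without the library labelled KL2 IFN-β were chosen after the data had been seen. Of the counts and the correlation, 170 alternatives stayed close, 31 moved and 1 reversed. Counts taken as close include 0 that stayed 0. They also include changes as large as 185 to 277 genes with IFN-β in KL, and 220 to 301 with IFN-β, in DESeq2 with established whole reads. Of list tests 547 stayed on their side of the threshold, 55 fell short, 10 passed and 1 reversed (cholesterol synthesis in KL, adjusted p = 0.0438 without KL2 IFN-β). Of single genes 1790 stayed, 231 fell short, 3 passed and 9 moved. The cause was not tested except where fewer genes or libraries are stated.

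Leaving out 1 library gave 189 to 269 genes with IFN-β, 132 to 261 in KL, 100 to 118 in KP and 0 in KP minus KL. It gave 150 to 1214 for KP against KL, 0 to 23 with STING, 0 to 322 in KL, 0 in KP and 0 to 179 in KP minus KL. Leaving out 1 line gave 49 to 120 for STING minus IFN-β and r of 0.223 to 0.262.

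KP against KL moved to 105 in edgeR with established whole reads, against 391 in edgeR with every library, to 1132 in DESeq2 with every library and to 1552 in the STING table. DESeq2 with every library gave 283 genes with IFN-β in KL, 1 for the IFN-β effect in KP minus KL, 121 with STING in KL and 66 for the STING effect in KP minus KL. With established whole reads it gave 2 with STING, 119 in KL, 1 in KP and 52 in KP minus KL. The block gave 597 with STING in KL and 7 in KP minus KL. Limma without the trend gave 1 and 1. STING minus IFN-β moved to 59 with a minimum mean of 50 (fewer genes) and to 65 without pairing. The correlation moved to 0.24 with that minimum and reversed to -0.0307 with disjoint lines, which share no control. The block without line KL2 was not run for STING, since it leaves 1 residual degree of freedom.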

Other observations

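The values in this part were singled out after the results had been seen.

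Sting1, which encodes the sensor adaptor STING, was lower in KP than in KL empty libraries, at 30.5 ± 35.6 against 118 ± 62.7 normalised counts (SD, n = 3 each; log2 -2.42 ± 0.81), which missed the threshold in limma (adjusted p = 0.111). Leaving out 1 library gave -3.34 (adjusted p = 0.0485, without KP1 empty) to -1.73 (0.282, without KP2 empty), and it was called in 1 of 6 runs. In the STING table, which lacks KL3 and KP1, the difference was -2.93 (adjusted p = 0.00696), but the only KL lines there, KL1 and KL2, may be the same cell line. The same doubt touches the main comparison, which includes their empty libraries. With IFN-β its level was 74.0 ± 66.0 in empty and 142 ± 120 in IFN-β libraries (SD, n = 6 each; adjusted p = 0.914). The kinase Ikbke, which acts downstream of STING, was also lower in KP (-2.27 ± 0.31, adjusted p = 0.00278).

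With cell line as a block, 7 genes had a lower STING effect in KP than in KL: Psap, Ran, Rpl39-ps, Phgdh, Rpl38-ps2, Mir703 and Hspe1-rs1. Phgdh, the entry enzyme of serine synthesis, was at 34.7 and 109 normalised counts in KL empty and STING libraries and at 342 and 200.1 in KP (means, n = 2 each). The nuclear transport GTPase gene Ran was at 403 and 1226 in KL and at 1576 and 1260.4 in KP.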
